A study of Mus musculus with 13 samples.

How the data were processed

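The samples were pieces of infrarenal abdominal aorta from male C57BL/6J mice aged 8 weeks at surgery, taken 28 days after the operation, per the labels. For 6 samples (AAA, abdominal aortic aneurysm) a sponge with 5 µL of porcine pancreatic elastase lay on the vessel for 5 min. The mice then drank water with 0.2% β-aminopropionitrile, an inhibitor of the lysyl oxidases that crosslink elastin and collagen. For 7 samples (Sham) the elastase had first been inactivated by heat at 100 °C for 30 min, and the labels name no β-aminopropionitrile for them. As far as the labels tell, the comparison is of active elastase together with the inhibitor against neither. Total RNA was made into mRNA libraries with a BGI kit whose strand setting is not given in the sources used here.

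The authors deposited 1 table of RSEM expected counts, with 18321 gene symbols and 13 libraries. Per the submitters' processing notes, Bowtie2 and RSEM 1.3.1 were used with the mouse build GRCm39; the Bowtie2 version and the gene annotation are not given in the sources used here. RSEM divides reads that fit several genes among them, so estimated counts need not be whole. Within 0.001 of a whole number, 4.77% to 6.08% of values per library were not whole. Near-identical genes such as Hba-a1, Hba-a2 and Ccl21a had values that were not whole in 13 libraries, so how their reads were divided is uncertain. No coordinates are given, because the annotation at hand is of another mouse build; its RefSeq table (GRCm38.p6) served only to match older symbols and gene types.

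The library totals ran from 11970300 to 13287700 expected counts in Sham and from 13563800 to 14385300 in AAA, so every AAA library was deeper than every sham library. Expected counts were rounded to whole numbers. Genes were kept with filterByExpr of edgeR 4.0.16 in R 4.3.3, which left 14170, and libraries were scaled by TMM. Each gene was tested with edgeR's quasi-likelihood F-test (glmQLFit, glmQLFTest) on a design with the group alone, and p-values were adjusted by Benjamini-Hochberg over all genes tested, with calls at adjusted p below 0.05. Levels are CPM (counts scaled to a common library size after TMM), computed here. A fold against a group with 0 counts was computed against a floor of 3 counts over the group, and folds with 1 to 3 counts carry a 95% exact binomial interval. These intervals and floors cover counting error only, since reads without molecular identifiers are not independent molecules.

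Before the data were examined, 42 gene lists were fixed, 24 of functions and 18 of cell type markers, with 798 distinct symbols, of which 778 were matched in the table. Lists with at least 5 tested members, 39 of them, were tested with camera of limma 3.58.1 at its preset inter-gene correlation of 0.01, with Benjamini-Hochberg adjustment over the lists. Camera asks whether a list moves against all other tested genes. A list's score in a library is the mean log2 CPM of its tested members, with a prior count of 1. The naming rule was also fixed then. It took the 6 largest rises and 6 largest falls among called genes with an average log2 CPM of at least 1 and no overlap between the groups, leaving out predicted genes and pseudogenes. It took the called members with the smallest p of each list, up to 3 for functions and up to 2 for markers, or the member with the smallest p where none was called. Cyp7a1, Cyp27a1, Cyp7b1, Nr1h4, Gpbar1, Lox and Eln were named in any case. Genes named outside this rule were chosen after their values were seen, and are said to be so.

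The test was tested on simulated data: counts for 14170 genes were drawn from the means and library sizes of this comparison, with 50 genes changed at each of 4 fold sizes. The quasi-likelihood test called 48% of genes changed 1.5-fold, 76% of those changed 2-fold, 94% of those changed 4-fold and 98% of those changed 8-fold, and 10 of the unchanged genes. Far fewer genes were changed there than were called in the data, where 62.5% of those tested were called. The Benjamini-Hochberg cutoff depends on that share, so these rates need not hold for the data. Of 100 unchanged lists camera called 0, and it called the changed list higher. Genes were drawn independently, so this does not show how camera at the preset correlation treats lists whose members move together. In the data the estimated correlations of the lists ran from 0.04 (cartilage and bone) to 0.88 (skeletal muscle). The p-values measure the spread between samples, and the labels name each library as a sample of its own without giving a mouse number. No libraries were duplicates, since the chi-square over its degrees of freedom was 9.99 or more for each pair within a group.

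Alternatives were other scalings (DESeq2 size factors, library totals, upper quartile), no filter or a stricter one, DESeq2 1.42.0, limma-voom with and without sample quality weights, the replicate number as a block, leaving out each library, a stricter threshold, a fold threshold of 1.5, and camera with an estimated correlation or fry. Permutation tests and outlier checks ran in Python 3.11.15 with scipy 1.17.1 and pandas 2.3.3, and plots were drawn with matplotlib 3.10.9. Symbols fixed in the lists but not matched in the table were not analysed here, and some genes that the naming rule took are not reported here.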

Results

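The transcriptome of the infrarenal abdominal aorta was measured by RNA-seq in 7 samples from sham mice and 6 from mice with elastase-induced abdominal aortic aneurysm (AAA) at day 28. The title of the series names bile acid metabolism in aneurysm as its subject. Totals were 11970300 to 13287700 expected counts in the sham libraries and 13563800 to 14385300 in the AAA libraries. The most abundant gene was Acta2, smooth muscle actin, in each sham library. It was Eln, the elastin gene, in 5 AAA libraries and Col3a1 in AAA 4. The first principal component held 68.5% of the variance and parted the groups, and the second held 19.9%, with Sham 2 and Sham 5 at one end.

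The aneurysmal aorta differed from sham aorta in most of the genes tested: leukocyte, cytokine and cell cycle genes rose, while contractile smooth muscle, adipocyte and mitochondrial genes fell. Of 14170 genes, 4447 rose and 4408 fell in AAA, and 5315 were not called (edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment). More than 2-fold changes were found for 2172 genes that rose and 1616 that fell. In 3090 of the genes that rose and 2511 of those that fell the groups did not overlap, together 39.5% of the genes tested, against 0.117% by chance. Of the 39 lists tested with camera, 19 were called higher and 7 lower. With an estimated correlation, 7 lists were called higher and 0 lower. Against a fold of 1.5 the counts were 2416 higher and 1755 lower.

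The 6 largest rises taken by the naming rule were Cxcl5, Trem1, Jchain, Mmp13, Cd300lf and Acod1. Cxcl5, a neutrophil chemokine, had 0 counts over the 7 sham libraries and 36.7 ± 30.8 CPM (SD, n = 6) in AAA, at least 1108-fold higher. Trem1, a receptor of myeloid cells, also had 0 sham counts and was at least 304-fold higher. Acod1 had 1 sham count, with a ratio of 1150 (95% interval 206 to 45447), and Cd300lf had 3, with a ratio of 815 (95% interval 279 to 3955). Jchain, which joins antibody chains, rose by 9.73 ± 0.56 on the log2 scale (SE) and the collagenase gene Mmp13 by 9.34 ± 0.76. The largest falls were in Ucp1, the uncoupling protein of brown fat, which fell from 444 ± 333 CPM (SD, n = 7) to 0.447 ± 0.540 CPM (SD, n = 6), in Cidea (log2 fold change −7.65), Otop1 (−7.50), Slc27a2 (−6.58) and Gys2 (−6.43). Olfr224 had 1 count over the AAA libraries, a ratio of 569 in favour of sham (95% interval 102 to 22525).

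Bile acid genes changed in both directions. Of the 13 tested genes of bile acid synthesis, 3 rose, 5 fell and 5 were not called, and the counts were 3 and 5 when adjusted over the list alone. Over all genes tested, 62.5% were called. The share of members called in the bile acid synthesis, transport and receptor lists was close to that, so these counts do not set the lists apart. Ch25h, which makes 25-hydroxycholesterol, rose from 0.650 ± 0.381 CPM (SD, n = 7) to 28.2 ± 9.94 CPM (SD, n = 6), a log2 fold change of 5.40 ± 0.36 (SE; adjusted p = 1.75e-08, edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment). Cyp7b1, the oxysterol 7α-hydroxylase, rose by 3.56 ± 0.36 and Cyp27a1, the sterol 27-hydroxylase of the acidic pathway, by 0.57 ± 0.13, each higher than the sham mean in 6 of 6 AAA libraries. Slc27a2, an acyl-CoA synthetase that is also in the brown adipocyte list, fell by 6.58 ± 0.66, and Abcd3, a peroxisomal transporter, fell by 1.01 ± 0.09. Slc27a2 had 13 counts over the AAA libraries, with 0.635 CPM in AAA 2 against 0 to 0.142 CPM in the others, and without AAA 2 its log2 fold change was −7.87. Pex5, Scp2 and Hsd17b4, peroxisomal genes chosen after their values were seen, fell by 0.59, 0.92 and 0.53. The list median was −0.28, and camera did not call the list (adjusted p = 0.462; adjusted p = 0.784 with an estimated correlation). Of 7 members below the low-count filter, 2 were called lower and 0 higher without it, by edgeR's quasi-likelihood test. Cyp7a1, the rate-limiting enzyme of the classic pathway in liver, was not analysed here.

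Among bile acid transporters above the low-count filter, those that changed rose, while several below it had fewer counts in AAA. Of 6 tested members, 4 rose, 0 fell and 2 were not called, with the same counts when adjusted over the list alone. Abcc3, an exporter of conjugated bile acids, rose from 1.34 ± 0.49 CPM (SD, n = 7) to 23.7 ± 3.35 CPM (SD, n = 6), a log2 fold change of 4.13 ± 0.22 (SE; adjusted p = 1.76e-09, edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment). Slc10a6, a carrier of steroid sulfates, rose by 2.12 ± 0.16, and Slco2b1, an organic anion carrier, rose by 0.66 ± 0.17. The list median was 0.61, and camera called the list higher at adjusted p = 0.0465, close to the threshold, but not with an estimated correlation (adjusted p = 0.302 with an estimated correlation). The call was lost in 7 of 13 fits that left out 1 library (Sham 3, 6 or 7, or AAA 2, 3, 5 or 6), at adjusted p from 0.0529 to 0.0681, and without a low-count filter the median was −0.66. The median was 1.02 with quality weights, 0.96 without Sham 2 and Sham 5 and 0.95 without Sham 1 and 2 and AAA 1 and 2, each called higher by camera (adjusted p = 0.0161, 0.0132 and 0.0275). Below the filter lay 9 more members, of which 8 took a lower share of the counts in AAA. Without the filter, 3 of the 9 were called lower and 0 higher in edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment, all chosen after their values were seen. Abcc2 had 101 counts over the 7 sham libraries and 11 over the 6 AAA libraries (adjusted p = 0.0414 in edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment), Slco1a4 had 63 and 8, and Slco1b2 had 14 and 1. Sham 2 and Sham 5 held 32 and 60 of the sham counts of Abcc2.

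Bile acid receptors and their partners also went both ways. Of 13 tested members, 4 rose, 5 fell and 4 were not called; adjusted over the list alone, 4 rose and 7 fell. Vdr, the vitamin D receptor that also binds lithocholic acid, rose by 4.37 ± 0.32, S1pr2, a receptor of sphingosine-1-phosphate and conjugated bile acids, by 1.40 ± 0.12, and Gpbar1, the membrane bile acid receptor, by 1.73 ± 0.20. Gpbar1 was low in both groups, at 0.723 ± 0.183 CPM (SD, n = 7) and 2.42 ± 0.44 CPM (SD, n = 6). Adcy9, an adenylyl cyclase, fell by 1.37 ± 0.10. Nr1h4, the nuclear bile acid receptor FXR, was below the low-count filter, with 13 counts over the 7 sham libraries and 81 over the 6 AAA libraries; without the filter its log2 fold change was 2.68 ± 0.52 (adjusted p = 0.000564, edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment). The list median was −0.26 and the mean 0.20, so they differ in sign, and camera, with direction down, did not call the list (adjusted p = 0.807). In the same libraries the list medians of macrophage and brown adipocyte markers were 3.25 and −4.84. The hepatocyte list had a median of 0.06 over its 5 tested members and −1.53 without the filter, where 9 of the 10 members below it took a lower share of the counts in AAA, like the bile acid transporters below the filter.

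**Figure D1:**
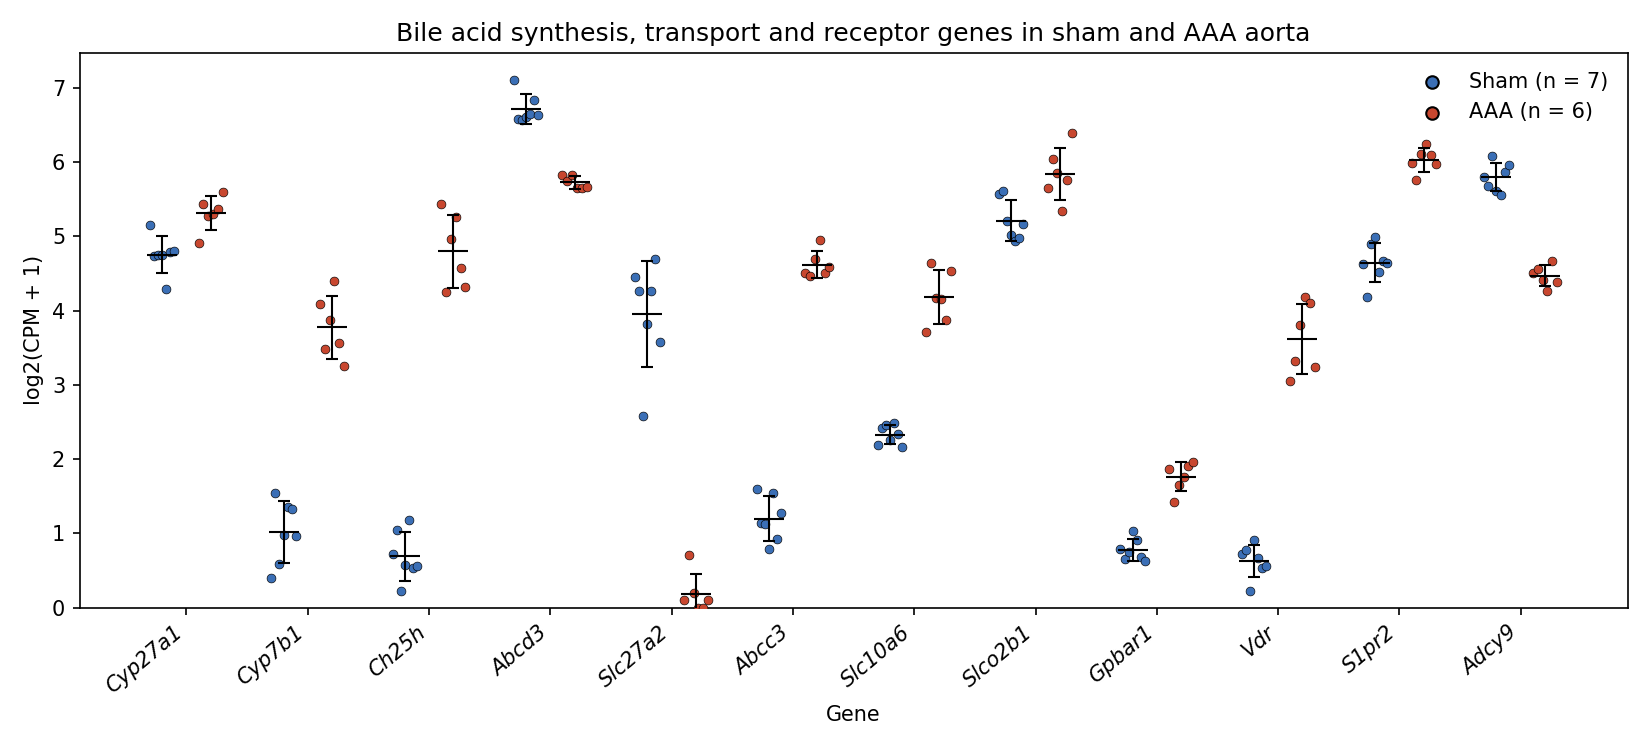
Levels of 12 bile acid genes as log2(CPM + 1), 1 point per library, in 7 sham and 6 AAA libraries; bars are the mean and SD of the group. Abcc3, Ch25h, Cyp7b1 and Vdr were higher in every AAA library than in every sham library, and Slc27a2 and Adcy9 were lower.

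Genes of cholesterol synthesis and uptake fell together. Of 23 tested members, 19 fell, 1 rose and 3 were not called, with a median log2 fold change of −1.56; adjusted over the list alone, 19 fell and 1 rose. Sc5d, an enzyme of cholesterol synthesis, fell by 1.56 ± 0.21 (SE) and Srebf2, the transcription factor of the pathway, by 1.17 ± 0.14. Camera called the list lower (adjusted p = 0.000223; adjusted p = 0.51 with an estimated correlation). White adipocyte markers were lower in the same libraries, with a list median of −2.62. The cholesterol score was 6.06 to 6.32 in Sham 2, 4 and 5 and 4.80 to 5.19 in the other sham libraries, against 4.23 to 4.34 in AAA. Sham 2 and Sham 5 also had the highest Schwann cell and neuron scores, and without them 19 members fell and 1 rose, with a median of −1.31. Of 20 lipid-loaded macrophage genes, 13 rose, 4 fell and 3 were not called (13 and 4 adjusted over the list alone), with a median of 1.29; the list shares Fabp4 and Lpl with the white adipocyte list. Of 16 macrophage markers, 15 rose in the same libraries, with a median of 3.25. Trem2, a lipid-sensing receptor of macrophages, rose by 5.38 ± 0.23, Lgals3 by 3.17 ± 0.18 and Npc2, which carries cholesterol out of lysosomes, by 1.62 ± 0.09. Camera called this list higher (adjusted p = 0.000778; adjusted p = 0.19 with an estimated correlation).

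Contractile smooth muscle genes fell without exception. All 24 tested members fell, also adjusted over the list alone, with a median log2 fold change of −2.20. Hspb6, a small heat shock protein of muscle, fell from 179 ± 43.9 CPM (SD, n = 7) to 23.9 ± 5.08 CPM (SD, n = 6), a log2 fold change of −2.90 ± 0.19 (SE; adjusted p = 1.78e-08, edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment). Ppp1r14a, an inhibitor of myosin phosphatase, fell by 2.51 ± 0.21 and Tpm2, a tropomyosin, by 2.16 ± 0.20. Camera called the list lower (adjusted p = 2.44e-12; adjusted p = 0.174 with an estimated correlation). Endothelial markers in the same libraries had a median of −0.06, fibroblast markers 0.94 and macrophage markers 3.25.

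Matrix genes rose. Of 21 elastic fibre and crosslinking genes, 16 rose, 3 fell and 2 were not called (16 and 3 adjusted over the list alone), with a median of 1.03. Lox, the crosslinking enzyme that β-aminopropionitrile inhibits, rose from 339 ± 101 CPM (SD, n = 7) to 1055 ± 171 CPM (SD, n = 6), a log2 fold change of 1.64 ± 0.19 (SE; adjusted p = 4.72e-06, edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment). Eln rose by 0.75 ± 0.24, with adjusted p = 0.014 in edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment, and was higher than the sham mean in 5 of 6 AAA libraries. Ltbp2, an elastic fibre protein, rose by 2.62 ± 0.17. Of 28 collagens and matrix glycoproteins, 17 rose, 4 fell and 7 were not called (17 and 4 adjusted over the list alone), with a median of 0.87, among them Col8a1 (4.53 ± 0.14), Col12a1 (4.66 ± 0.24) and Thbs1 (3.80 ± 0.14). Of 24 matrix proteases, 23 rose and 1 fell, with a median of 2.07 and the same counts adjusted over the list alone, among them Mmp2 (2.47 ± 0.12), Ctss, the cathepsin of antigen-presenting cells (5.54 ± 0.26), and Adamts4 (4.32 ± 0.23). Of 20 cartilage and bone genes, 14 rose, 3 fell and 3 were not called (14 and 4 adjusted over the list alone), with a median of 2.09. Col2a1, the cartilage collagen, rose by 8.32 ± 0.35 and Runx2, a transcription factor of bone formation, by 3.82 ± 0.13. The cartilage and bone list shares 1 member with the lipid-loaded macrophage list, and the protease list shares 1 with the neutrophil list.

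Camera called each of these matrix lists higher, none of them with an estimated correlation. The elastic fibre list had adjusted p = 0.00197 (adjusted p = 0.302 with an estimated correlation) and the collagen list 1.67e-05 (adjusted p = 0.258 with an estimated correlation). The protease list had adjusted p = 1.83e-11 (adjusted p = 0.0668 with an estimated correlation) and the cartilage and bone list 0.000331 (adjusted p = 0.0524 with an estimated correlation). The call of Eln was lost without Sham 1 and 2 and AAA 1 and 2, where its log2 fold change was 0.66 (adjusted p = 0.107 in edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment). Of 13 protease inhibitors, 7 rose, 3 fell and 3 were not called (8 and 3 adjusted over the list alone), with a median of 0.51 and no call by camera (adjusted p = 0.179). Timp1 and Timp4, both inhibitors of metalloproteinases, moved apart, at log2 fold changes of 4.89 ± 0.39 and −2.69 ± 0.21. Fibroblast markers moved with these lists: 12 of 17 rose, 3 fell and 2 were not called (12 and 3 adjusted over the list alone), with a median of 0.94 (camera adjusted p = 0.0064; adjusted p = 0.457 with an estimated correlation), with Lum (3.17 ± 0.22) and Meox1 (2.04 ± 0.14) among them. The fibroblast list shares 3 members, Lum, Dcn and Col14a1, with the collagen list.

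Immune cell markers rose in every leukocyte list but the mast cell list. Of 16 macrophage markers 15 rose and 1 was not called, of 10 neutrophil markers 10 rose, of 20 T and NK cell markers 20 rose, of 13 B and plasma cell markers 13 rose, and of 14 dendritic cell markers 13 rose and 1 was not called, with the same counts adjusted over each list alone. The list medians were 3.25, 6.39, 5.65, 4.43 and 4.49 on the log2 scale, and the neutrophil median was 6.13 with 2 members without sham counts set to their bounds. C1qb, a complement subunit of macrophages, rose from 41.7 ± 9.21 CPM (SD, n = 7) to 651 ± 65.7 CPM (SD, n = 6). S100a9, a neutrophil protein, rose by 9.07 ± 0.56, Cd5, a surface glycoprotein of T cells, by 5.08 ± 0.20, Blnk, a B cell adaptor, by 4.10 ± 0.17 and H2-Ab1, an MHC class II chain, by 4.90 ± 0.15. Camera called all 5 lists higher, at adjusted p from 2.14e-22 (dendritic cell) to 1.3e-06 (neutrophil). With an estimated correlation the macrophage, T and NK cell and dendritic cell calls held (adjusted p = 0.0443, 0.0211 and 0.00651 with an estimated correlation), and the neutrophil and B cell calls did not (adjusted p = 0.174 with an estimated correlation, for each). Of 7 mast cell markers, 2 rose, 2 fell and 3 were not called (2 and 2 adjusted over the list alone), with a median of 0.33 and camera direction down (adjusted p = 0.932). The mast cell list shares 1 member, which rose, with the neutrophil list.

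Inflammatory and growth genes rose with the leukocyte markers, and the macrophage list shares Csf1r with the chemokine list, C1qa and C1qb with the complement list, and Cd68 and Fcgr1 with the lysosome list. Of 30 chemokines, cytokines and receptors, 29 rose and 1 was not called, with a median of 5.55, among them Cxcl16 (3.92 ± 0.15) and Csf1r (3.25 ± 0.15). Of 14 inflammasome and pyroptosis genes, 11 rose and 3 were not called, including Gsdmd, the pore-forming gasdermin D (2.42 ± 0.12), and Aim2, a sensor of cytosolic DNA (4.64 ± 0.23). All 23 interferon response genes rose, with Irf7 at 5.19 ± 0.26. Of 18 complement genes 17 rose and 1 fell, of 28 cell cycle genes 27 rose and 1 fell (Top2a 4.36 ± 0.23), and of 27 lysosome and phagosome genes 23 rose, 2 fell and 2 were not called (Fcgr1 6.16 ± 0.23), each with the same counts adjusted over the list alone. The medians of these lists were 2.55, 3.08, 3.15, 3.58 and 1.18 in the order given after chemokines. Camera called all 6 lists higher. With an estimated correlation the chemokine, inflammasome, complement and lysosome calls held (adjusted p = 0.0417, 0.0211, 0.0417 and 0.0477 with an estimated correlation), and the interferon and cell cycle calls did not (adjusted p = 0.0999 with an estimated correlation, for each).

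**Figure D2:**
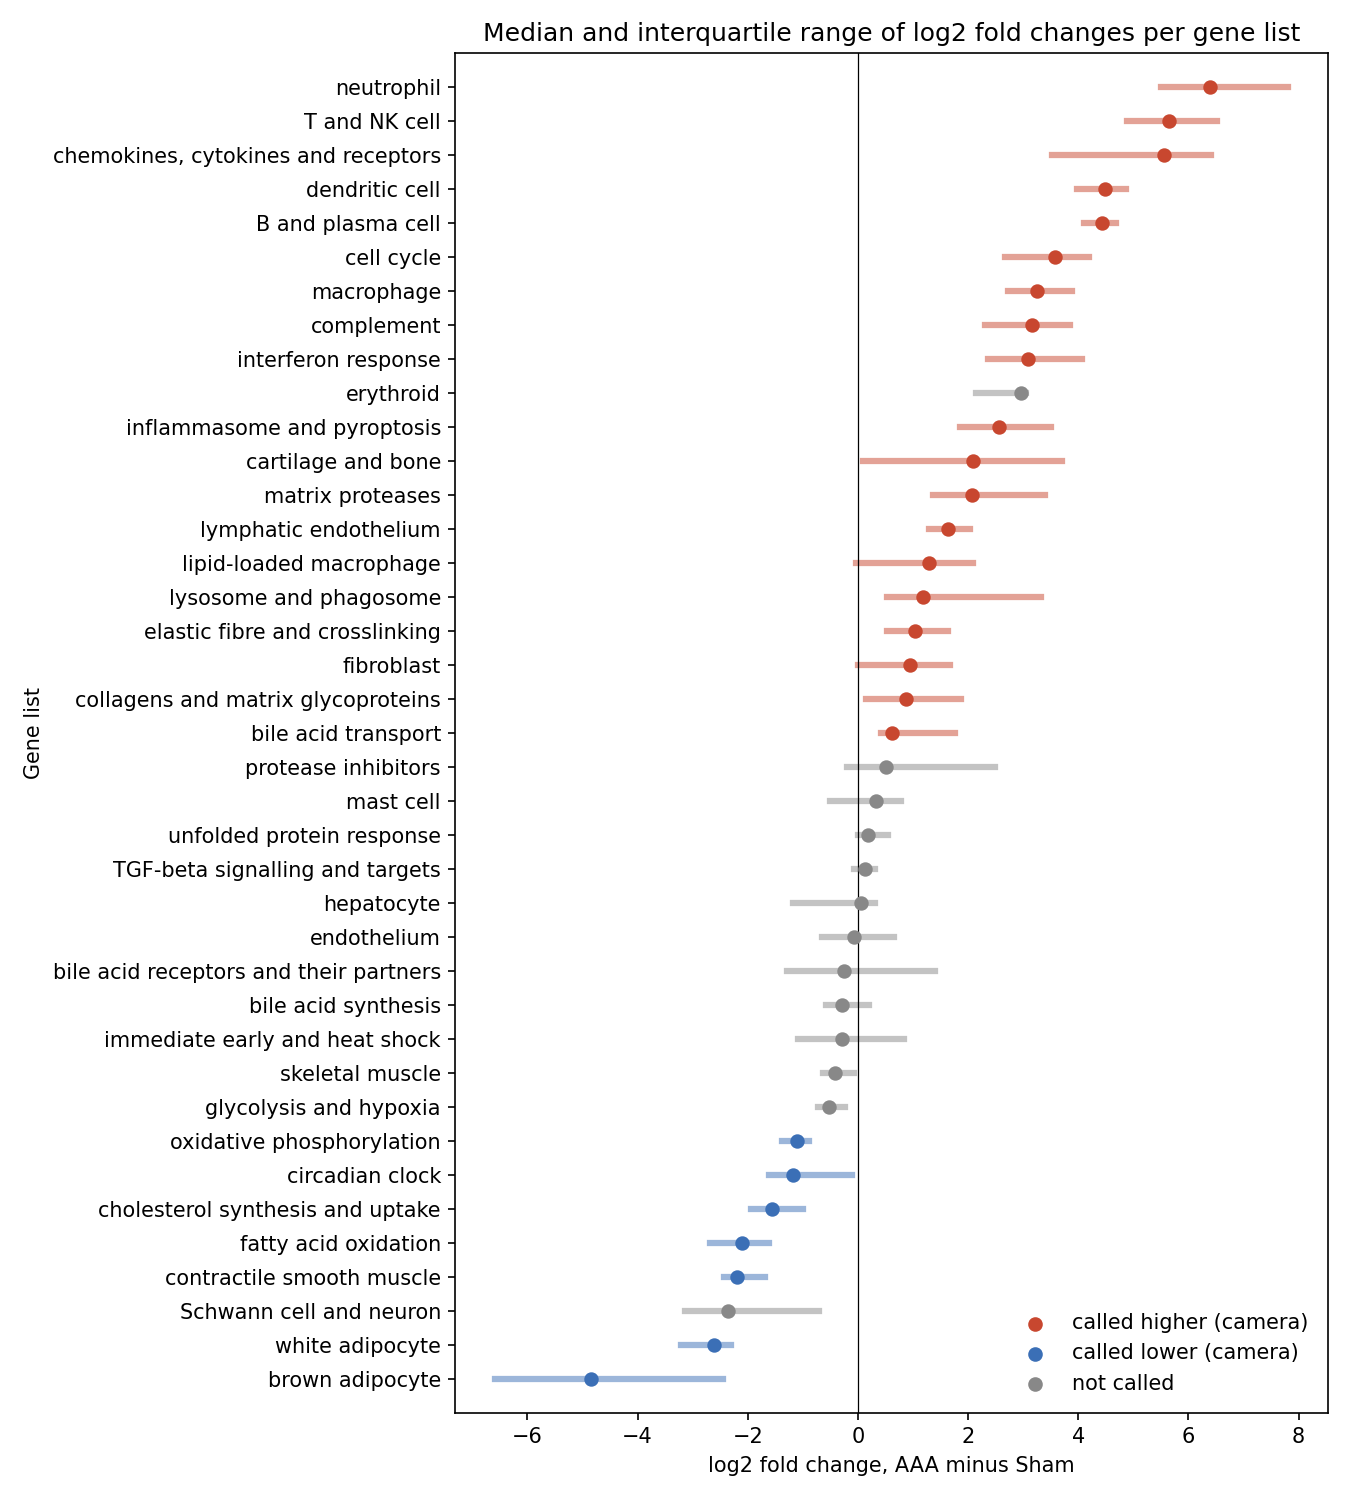
Median log2 fold change (AAA minus Sham; points) and interquartile range (bars) of the tested members of 39 gene lists, coloured by the camera call at the preset correlation. Neutrophil markers had the highest median, 6.39, and brown adipocyte markers the lowest, −4.84.

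Fat and mitochondrial genes fell. All 13 brown adipocyte markers and all 19 white adipocyte markers fell, also adjusted over each list alone, with medians of −4.84 and −2.62. Cidea fell by 7.65 ± 0.46, Fabp4, a fatty acid carrier, from 1438 ± 535 CPM (SD, n = 7) to 234 ± 60.3 CPM (SD, n = 6), and Aqp7, the glycerol channel of fat cells, by 3.37 ± 0.31. Of 23 fatty acid oxidation genes, 22 fell and 1 rose, with a median of −2.10, among them Cpt1b (−4.68 ± 0.34), the muscle and brown fat carnitine transferase, and Acadm (−2.41 ± 0.21). All 27 oxidative phosphorylation and citrate cycle genes fell, with a median of −1.11, among them Cs, citrate synthase (−1.49 ± 0.14). The counts of both lists were the same adjusted over each list alone. Camera called the brown (adjusted p = 1.92e-10) and white (3.09e-08) adipocyte, fatty acid oxidation (1.22e-10) and oxidative phosphorylation (4.51e-10) lists lower, none of them with an estimated correlation (adjusted p = 0.0999, 0.258, 0.242 and 0.258 with an estimated correlation). Of 22 glycolysis and hypoxia genes, 12 fell, 2 rose and 8 were not called, also adjusted over the list alone, with a median of −0.52 and no call by camera (adjusted p = 0.0659). Camera called this list lower under 8 alternatives, among them leaving out Sham 3, Sham 7 or AAA 4, at adjusted p from 0.0241 to 0.0482, but not with an estimated correlation (adjusted p = 0.596 with an estimated correlation). The rotation test fry, which tests a list against no change and not against other genes, called it lower (adjusted p = 0.00992 in fry). Bnip3 fell by 1.43 ± 0.18, while Car9, a carbonic anhydrase induced by low oxygen, rose by 3.51 ± 0.28.

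TGF-beta genes and the endothelium moved in both directions. Of 22 TGF-beta signalling genes and targets, 7 rose, 3 fell and 12 were not called (7 and 3 adjusted over the list alone), with a median of 0.12 and camera adjusted p = 0.387. Over all genes tested 62.5% were called, a larger share than in the TGF-beta list. Tgfb1, the growth factor, rose by 1.43 ± 0.10, its receptor gene Tgfbr2 by 1.22 ± 0.12 and Tgif1, a repressor of Smad targets, by 2.06 ± 0.07. Of 18 endothelial markers, 8 rose, 7 fell and 3 were not called (8 and 7 adjusted over the list alone), with Emcn at 1.32 ± 0.16 and Pecam1 at −1.18 ± 0.13. The endothelial median was −0.06, its mean 0.01, and the camera direction down (adjusted p = 0.65). Of 8 lymphatic endothelial markers, 7 rose and 1 fell, also adjusted over the list alone, with a median of 1.64 (camera adjusted p = 0.000778; adjusted p = 0.117 with an estimated correlation), led by Pdpn (3.33 ± 0.18) and Ccl21a (2.75 ± 0.20), which shares reads with near-identical copies. The list shares Lyve1 with the macrophage list, whose median was 3.25 in the same libraries.

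Neuronal and skeletal muscle transcripts varied widely between libraries within each group. The Schwann cell and neuron score was 7.13 in Sham 2 and 7.50 in Sham 5, against 0.77 to 5.13 in the other sham libraries and 1.24 to 4.74 in AAA. Of 20 members, 5 fell and 15 were not called (3 fell adjusted over the list alone), among them Uchl1, a neuronal hydrolase, which fell by 2.46 ± 0.71. Its level was 501 CPM in Sham 2 and 995 CPM in Sham 5, against 55.7 to 129 CPM in the other sham libraries and 28.5 to 76.3 CPM in AAA, and without Sham 2 and Sham 5 its log2 fold change was −0.77, still called lower. The list median was −2.36 with all libraries (camera adjusted p = 0.328) and 0.24 without Sham 2 and Sham 5, where 3 members rose and 3 fell. The skeletal muscle score was highest in Sham 2 (6.77) and AAA 2 (6.27), and of 18 members 1 fell (Casq1, by 3.59 ± 0.61) and 17 were not called, also adjusted over the list alone, with a median of −0.41 (camera adjusted p = 0.462). Casq1 was at 14.7 CPM in AAA 1 and 44.2 CPM in AAA 2, against 2.92 to 5.72 CPM in the other AAA libraries, and its log2 fold change was −4.59 without AAA 2 and −5.26 without Sham 1 and 2 and AAA 1 and 2. Without Sham 2 and Sham 5, an alternative chosen after seeing the data, 4651 genes rose and 4368 fell, and without Sham 1 and 2 and AAA 1 and 2, those with the highest muscle scores in their groups, 4172 rose and 3865 fell.

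**Figure D3:**
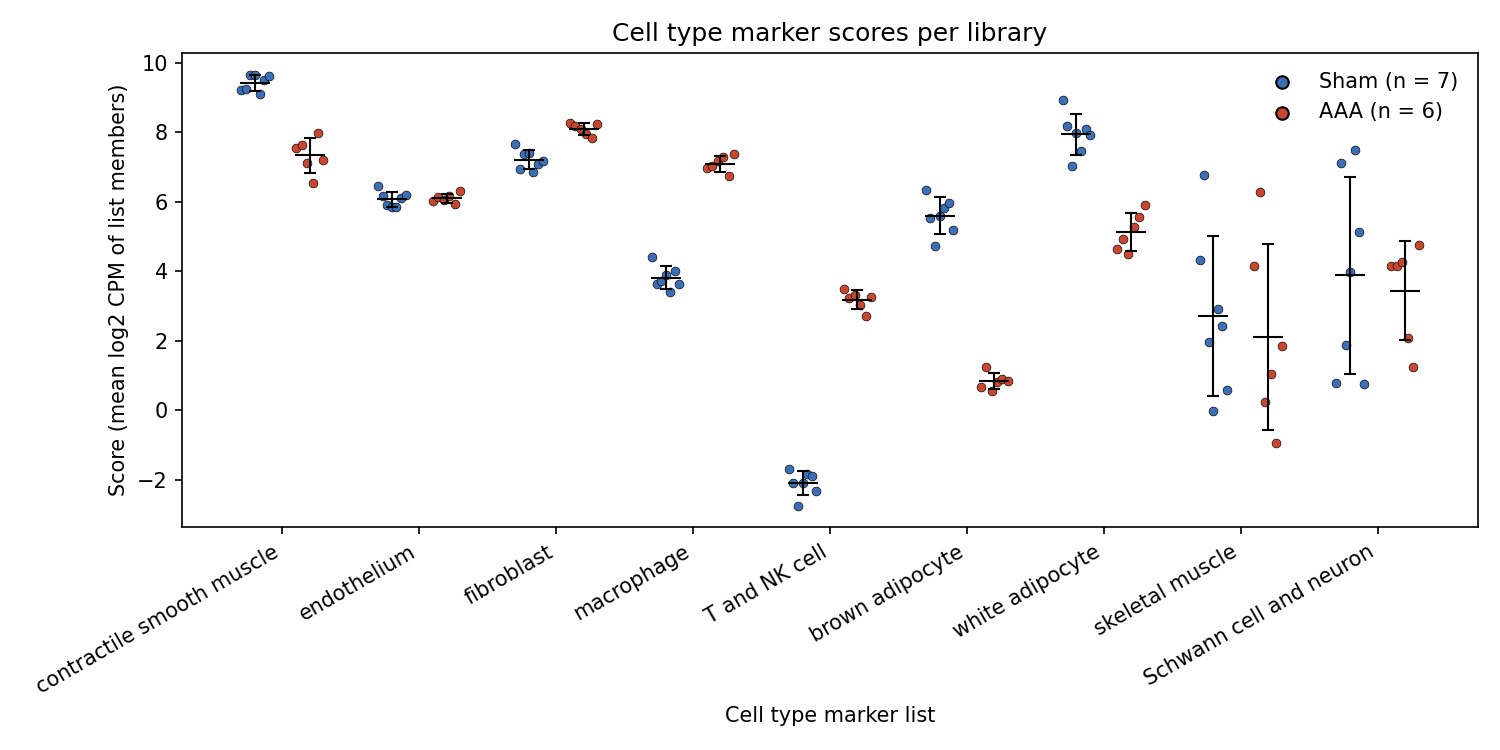
Cell type marker scores (mean log2 CPM of the list's tested members) per library in 7 sham and 6 AAA libraries; bars are the mean and SD of the group. Contractile smooth muscle and both adipocyte scores were lower in every AAA library than in every sham library, endothelial scores overlapped, and the Schwann cell and neuron score was highest in Sham 5 and Sham 2.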

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

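The flags below follow rules set before the data were examined. A library was flagged where its gap to the nearest other library of its group exceeded Dixon's 95% critical value. There were 18 such flags in 312 groups, and chance flags about 1 in 20, or 15.6.

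Among named genes, Sham 1 stood above the other sham libraries for Cd74 (189 CPM), Oas2 (6.79 CPM), Mmp13 (0.242 CPM) and Sdhc (215 CPM), and these flags, 4 in all, are the most of any library. Sham 4 stood high for Acod1 (0.081 CPM) and Wt1 (0.403 CPM), Sham 5 low for Atf3 (31.6 CPM) and Sham 7 low for Star (0.789 CPM). In the AAA group, AAA 4 stood high for Ucp1 (1.52 CPM) and Olfr224 (0.073 CPM), AAA 2 high for Slc27a2 (0.635 CPM) and AAA 1 low for Srebf2 (70.0 CPM). Acod1, Olfr224 and Mmp13 rest on few counts in the flagged libraries.

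Among list scores, the mesothelium score was high in Sham 4 (1.70), the pancreatic acinar score high in Sham 5 (2.80) and the kidney tubule and adrenal score low in Sham 7 (−0.47). The protease inhibitor score was high in AAA 1 (8.64), and AAA 5 had a high circadian clock score (5.03) and a low dendritic cell score (5.08).

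Of 100 splits of the 13 libraries into 7 and 6, drawn from 1716 and with the real one included, 1 called as many genes as the real split, which called 8855. A random grouping is thus an unlikely source of the count. A mixed split puts the difference between the groups inside each of its sides, so low counts there follow from that difference. The splits do not bear on anything else that differed along with the groups. The highest of the other splits called 7429; it put 6 sham libraries against the AAA libraries and 1 sham library. Of the other splits 98 called 0 genes.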

How the results depend on the processing

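Alternatives without Sham 2 and Sham 5, without Sham 1 and 2 and AAA 1 and 2, and with counts thinned to the smallest total were chosen after seeing the data. Over the fits that left out 1 library, 3991 to 4429 genes rose and 4057 to 4745 fell, and at least 8237 of the 8855 calls remained. Against a fold of 1.5, 2416 genes rose and 1755 fell, which follows from the threshold. Thinned counts gave 4400 and 4389. No clear pairing of the samples by replicate number was found. Correlations of same-numbered samples ran from −0.48 to 0.43, and no 2 of the same number were each other's best match. The skeletal muscle score, however, was highest in numbers 1 and 2 of both groups (4.33 and 6.77 in Sham, 4.16 and 6.27 in AAA). A link between same-numbered samples was therefore not excluded. The replicate block on libraries 1 to 6 gave 4154 genes higher and 3838 lower, against 4310 and 4377 on those libraries without it. With an estimated correlation 7 lists were higher and 0 lower. The bile acid transport list lost its call with library totals (median 0.58), the replicate block (0.61), libraries 1 to 6 (0.59), thinned counts (0.62) and an estimated correlation (0.61), and over single left-out libraries its median ran from 0.51 to 0.72; its median was larger, and still called, with quality weights (1.02), without Sham 2 and Sham 5 (0.96) and without Sham 1 and 2 and AAA 1 and 2 (0.95); the cause was not tested. Without a filter it reversed to −0.66, where more low-count members entered. The bile acid synthesis and receptor lists were not called under any alternative run. Of 119 named genes tested, 116 kept their direction and side of the threshold under every alternative run for them. Eln lost its call with the replicate block (0.72) and without Sham 1 and 2 and AAA 1 and 2 (0.66), and Uchl1 with the replicate block (−1.76). Leaving out 1 library moved the fold of these named genes by over 1.5 times, with the call kept: Mmp13 (10.00 without Sham 1), Acod1 (10.38) and Wt1 (6.41) without Sham 4, Uchl1 (−1.65) without Sham 5, Slc27a2 (−7.87) and Casq1 (−4.59) without AAA 2, and Olfr224 (−9.53) and Ucp1 (−10.84) without AAA 4. Cpb1, never called, reversed with limma-voom (−0.0014), quality weights (−0.013) and the replicate block (−0.019), and ran from −0.14 to 0.29 over left-out libraries. Uncalled lists also reversed: hepatocyte without a filter (−1.53), on libraries 1 to 6 (−0.019), without Sham 1 and 2 and AAA 1 and 2 (−0.34) and over left-out libraries (−0.83 to 0.37), skeletal muscle with quality weights (0.46), without Sham 2 and Sham 5 (1.45) and over left-out libraries (−2.06 to 1.37), Schwann cell and neuron with quality weights (0.61) and without Sham 2 and Sham 5 (0.24), and endothelium without Sham 1 and 2 and AAA 1 and 2 (0.023). Uncalled lists were newly called in the same direction under some alternatives: glycolysis and hypoxia under 9 (1 of them fry), erythroid under 4 (1 of them fry), protease inhibitors under 2 (the replicate block and fry), and TGF-beta and the unfolded protein response under 1 each (fry). The causes were not tested. At this depth Nr1h4, with 13 sham counts, lay below the filter.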

Other observations

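Stress and signalling lists not described above went both ways. Of 20 immediate early and heat shock genes, 6 rose, 10 fell and 4 were not called, also adjusted over the list alone, with a median log2 fold change of −0.29 and camera adjusted p = 0.807. Socs3, the feedback inhibitor of cytokine signalling, rose by 4.21 ± 0.25 (SE), Junb by 2.99 ± 0.15 and Egr2 by 2.05 ± 0.21, while Atf3, also in the unfolded protein response list, had −1.28 ± 0.18. Of 21 unfolded protein response genes, 9 rose, 3 fell and 9 were not called, also adjusted over the list alone, with a median of 0.18 (camera adjusted p = 0.601). The share called in this list was below the 62.5% called over all genes tested. Sdf2l1, an endoplasmic reticulum protein, rose by 1.67 ± 0.16 and Pdia6, a disulfide isomerase, by 0.76 ± 0.11.

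Single markers of blood and neighbouring tissues changed, while camera called neither the erythroid nor the hepatocyte list and the other lists held too few tested members for it. Of 7 erythroid markers, 6 rose and 1 fell, also adjusted over the list alone, with a median of 2.97 (camera adjusted p = 0.165, and camera adjusted p = 0.596 with an estimated correlation). Camera called the erythroid list higher under 3 alternatives, among them leaving out Sham 1, and fry also called it higher (adjusted p = 0.000262 in fry). Hba-a1 rose by 3.09 ± 0.47, with reads that Hba-a2 shares. Aqp2, a water channel of the kidney collecting duct, rose by 4.72 ± 0.34, Star, a cholesterol carrier of steroid-making cells, by 2.02 ± 0.30 and Wt1, a gene of mesothelium and podocytes, by 5.60 ± 0.63. Of the kidney and adrenal list 2 of 3 tested members rose and 0 fell, and of the mesothelium list 2 of 4 rose and 1, Krt18, fell. Below the low-count filter, 7 of 8 kidney and adrenal members and 7 of 7 mesothelium members took a higher share of the counts in AAA, of which 3 and 0 were called higher without the filter. Of 5 hepatocyte markers, 1 rose (Ahsg, 2.13 ± 0.27), 1 fell (Cyp2e1, −1.86 ± 0.39) and 3 were not called, with a median of 0.06, a mean of −0.11 and camera adjusted p = 0.91. Of the 10 hepatocyte members below the filter, 9 took a lower share in AAA and 4 were called lower without it, and the median then was −1.53. Cyp2e1 had 45118 counts over the sham libraries and 11179 over the AAA libraries. Alb, below the filter and chosen after its value was seen, had 190 and 24. Whether any of these transcripts came from neighbouring tissues was not tested. Of 2 pancreatic acinar markers 0 were called, with Cpb1 at 0.13 ± 0.29, and of 11 below the filter 9 took a higher share in AAA and 0 were called.

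The tests in the 3 paragraphs that follow were chosen after the results they bear on were seen. If less of the same fat had been carried over, and fat were the only source of these transcripts, brown (median −4.84) and white adipocyte genes (−2.62) would fall alike. The brown minus white score differed by −1.95 between AAA (−4.29 ± 0.51, SD, n = 6) and Sham (−2.34 ± 0.38, SD, n = 7), with no overlap, a difference already seen in the medians. The white list shares Fabp4 and Lpl with the lipid-loaded macrophage list, so fat need not be its only source. The difference therefore does not exclude less of the same fat. Over the 7 sham libraries the oxidative phosphorylation score rose with the brown adipocyte score (Pearson r = 0.9464, exact permutation p = 0.00516, adjusted p = 0.00893 over 3 relations, and Spearman rho = 0.82, exact permutation p = 0.0341, adjusted p = 0.072). Without the 2 libraries farthest from the median r was 0.71. Fatty acid oxidation, whose list shares Ppara with the brown list, had r = 0.93 (0.62 without those libraries) and cholesterol synthesis r = 0.25 (exact permutation p = 0.59). A smaller part of brown fat in the sample is thus a candidate source of part of the mitochondrial fall. No correlation was computed for the white adipocyte score, but it too was highest in Sham 1 (8.91) and lowest in Sham 3 (7.02). So were the brown adipocyte (6.35 and 4.72) and oxidative phosphorylation scores (8.21 and 7.20), and brown fat is not singled out from fat as a whole. Whether fat around the vessel changed or was dissected differently was not tested.

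Contractile genes had a list median of −2.20, endothelial genes −0.06 and fibroblast genes 0.94. Leukocytes added to an otherwise unchanged wall would lower smooth muscle and endothelial genes alike, but the smooth muscle minus endothelium score differed by −2.11 between AAA (1.24 ± 0.58, SD, n = 6) and Sham (3.35 ± 0.36, SD, n = 7), with no overlap, a difference already seen in the medians. The endothelial list itself went both ways, with 8 of 18 members higher and 7 lower, so its score averages over opposite changes. A gain of endothelium, fewer smooth muscle cells and less contractile RNA per cell stay open, none of them tested.

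The circadian clock list had 12 genes lower, 2 higher and 4 not called (12 and 3 adjusted over the list alone), with a median of −1.17 (camera adjusted p = 0.00216; adjusted p = 0.174 with an estimated correlation). Hlf fell by 4.20 ± 0.30, Per2 by 3.00 ± 0.24 and Per3 by 1.86 ± 0.19, while Arntl (1.65 ± 0.20), chosen after its value was seen, rose. Collection at different times of day might part genes of the Arntl phase from those of the Per phase, and their medians differed by 2.16 on the log2 scale, with 8 of 9 Per-phase genes lower. Of the 3 Arntl-phase genes only 1 was called higher, Nr1d1 (−0.21 ± 0.19), chosen likewise, was not called, and the labels give no times, so time of day and the disease model cannot be told apart here. An effect of the changed cell types on these genes was not tested.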
